A study of Mus musculus with 6 samples.

How the data were processed

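RNA from 3 liver tumours and from the liver beside each of them was hybridised to Illumina bead arrays with 1 colour and a biotin label, per the labels. Tissues had been frozen directly after dissection. Samples were grouped as tumour or adjacent by their labels, and the number in each sample's title names the animal. For the tumour of animal 1316 the labels conflict, since another field gives a different animal number; the title was followed.

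The deposited intensity table holds a linear signal per probe and array for 45281 probes. It was not background-subtracted and not normalized between arrays, as its values show, and the table used here has no detection p-values or control probes. The submitters' processing notes name GenomeStudio, with no version or role. The deposited log2 table holds the authors' processed values of the same arrays. It ranks probes as the intensity table does in every array, and its sorted values differ by at most 0.00504 from the log2 of the mean sorted intensities, so its values are quantile-normalized without background subtraction, not centred per gene, with array medians of 7.26. The normalization is read from the values and not given in the sources used here.

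Intensities were background-corrected with normexp at an offset of 50, quantile-normalized between arrays and put on the log2 scale (limma 3.58.1 in R 4.3.3). Normalization with negative controls or detection p-values, planned for tables that hold them, could not be run. No probe was removed before testing. The background level of each array was estimated from its signals, as the mode of log2 signals plus 3 SDs mirrored from the values below the mode, and lay between 168.2 and 190.8 raw units. Between 13366 and 14467 probes were above it. Where a gene was below it on every adjacent array, the difference is given as "at least N-fold": the tumours' mean against the mean, per adjacent array, of the higher of the lowest normalized signal above background and the probe's own. A fall to below background on every tumour array is bounded in the same way, and no fold is given where neither bound can be formed. A fold change near background understates the true change because of the offset.

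Probe names came from the platform annotation, updated through gene identifiers with a gene table of assembly GRCm38.p6. A single symbol was found for 34885 probes and several for 18, and 10378 were not listed and stay unnamed. The update changed 0 symbols. A gene was read from 1 probe, the one with the highest mean signal over the 6 arrays, and other probes are mentioned where, for a gene named in the report, they turned the other way or changed by less than 1/2 as much.

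Tumours were compared with adjacent liver by lmFit and eBayes in limma, with Benjamini-Hochberg adjustment over all 45281 probes and a threshold of 0.05. Gene lists fixed before the data were examined (38 lists with at least 4 measured members) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Adjustment was over the 38 lists. The main fit had no block. By the sample titles each tumour and its adjacent liver came from the same animal, which another field contradicts for 1316, so the pairing rests on the titles. Their deviations from the group means correlated over 14107 expressed probes at 0.41, 0.25 and 0.09 for animals 1293, 1309 and 1316, against −0.27 to 0.03 for arrays of different animals. Deviations cancel out within a group, so positive values for the pairs push the others down, and that range is no independent reference. A fit with the animal as a replicate block (statmod 1.5.0 for the random form) is given for the counts of all genes and lists and, within lists, where it changes the members called higher or lower by 3 or more, or the call of a list or a named gene.

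Genes named in the text were chosen by a rule fixed beforehand: the 10 highest and 10 lowest log2 fold changes among called genes of the same direction in all 3 animals, the genes of the Dlk1-Dio3 cluster with Afp and Gpc3, and for each list up to 4 members with the smallest p in the majority direction and up to 2 called the other way. Mirg, a member of the Dlk1-Dio3 list, was not analysed here.

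The test was checked on simulated data for this comparison, with 45281 probes and 200 changed per run over 10 runs, under 3 models of a probe's spread. With each probe's own residual SD, 4.20%, 56.2%, 89.2% and 97.4% of log2 changes of 0.5, 1, 2 and 3 were recovered, and 3.44% of calls were false. With SDs drawn from the fitted variance distribution the shares were 5.80%, 89.2%, 99.8% and 100%, and 4.96% of calls were false. With shrunken SDs they were 17.4%, 96.6%, 99.8% and 100%, but 11.7% of calls were false, above the nominal rate, so the share of false calls depends on a spread that 3 arrays per group cannot settle. A list shifted by −0.5 was called in 10 of 10 runs of each model, and of 370 tests of unshifted lists 0 to 2 were called. Changes were planted only in probes that read well above background in adjacent liver, so the shares recovered do not hold for dim probes. Both groups were given the same spread and no pairing, so genes with a wider spread in tumours are not covered. These simulations hold no correlation between genes, so they do not show how camera behaves when list members vary together.

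The alternatives tried were the animal as a fixed or random block, no background correction, median scaling, the authors' processed values, another variance model, array weights, each array left out and animal 1316 left out, with an offset of 16, a filter on dim probes, the block without animal 1316 and the Dlk1-Dio3 list without Rian added after seeing the data. Figures were drawn with matplotlib 3.10.9.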

Results

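Liver tumours and the liver tissue beside them were compared on Illumina bead arrays, which read the abundance of a transcript as the brightness of a probe of matching sequence. The mice were of the C57BL/6J strain and had received 3e+10 particles of an adeno-associated virus (AAV) vector on the day after birth. The vector was built to target Rian, a long noncoding RNA gene of the imprinted Dlk1-Dio3 cluster, and carried the cytomegalovirus (CMV) element named in the labels. Tissue was taken 6 months later. The set holds 6 arrays: by the sample titles, 1 tumour and its own adjacent liver from each of 3 animals, numbered 1293, 1309 and 1316. Each array reads 45281 probes, of which 34885 carry a single gene symbol, for 19057 genes. Median raw signals lay between 138.4 and 160.5, and 29.5% to 32.0% of probes were above the background level estimated from each array. With 3 arrays per group, their number limits the precision of every value given here. No liver from uninjected animals was among the arrays, so the reference throughout is liver next to a tumour.

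The first comparison asked which genes differ between the tumours and the liver beside them. Slpi, a secreted inhibitor of leukocyte proteases, had the largest fitted increase among named genes, from 7.89 ± 0.40 in adjacent liver to 14.13 ± 0.36 in tumours (log2 signal, SD, n = 3), a log2 fold change of 6.24 (SE 0.21, adjusted p = 1.66e-08, limma). Gstp2, a glutathione transferase, rose by 5.74 (SE 0.25), the secreted serine protease gene Htra1 by 5.64 (SE 0.24), Cyp17a1 of steroid synthesis by 4.91 (SE 0.39), Mmd2 by 4.90 (SE 0.21) and Rsad2, an antiviral enzyme induced by interferon, by 4.85 (SE 0.47). Oxct1, the enzyme that lets tissues use ketone bodies and that hepatocytes normally lack, rose by 4.29 (SE 0.19). Cyp2a4, a steroid hydroxylase, and Ly6d were not above background in adjacent liver and were at least 44.4-fold and 16.7-fold higher in tumours. Wfdc12, of the same protein family as Slpi, rose by 4.93 (SE 0.18). Wfdc12 and Htra1 were each above background on 1 of 3 adjacent arrays.

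Among called genes the fitted decreases were smaller than the increases. This holds for the mean of 3 tumours and not for each tumour. Against its own adjacent liver, the tumour of animal 1316 had 174 genes lower and 162 higher by more than 2 log2 units. Lower and higher by as much were 6 and 106 genes in animal 1293 and 0 and 82 in animal 1309, without a test. The lowest called gene was Igfbp2, which encodes a binding protein for insulin-like growth factors, at −2.79 (SE 0.64, adjusted p = 0.0349, limma). It was followed by Csrp3 at −2.32 (SE 0.50), Gm4952 at −2.05 (SE 0.50), the glucuronosyltransferase gene Ugt1a5 at −2.01 (SE 0.41), Gm4956 at −2.01 (SE 0.46), Nlrp12 at −1.97 (SE 0.36), Ugt1a2 at −1.84 (SE 0.30), the carboxylesterase gene Ces1e at −1.80 (SE 0.36), Pigr, the receptor that carries immunoglobulin A into bile, at −1.79 (SE 0.42), and Cpsf4l at −1.78 (SE 0.44). The SDs of these genes were wider in tumours than beside them: Pigr read 11.81 ± 0.23 in adjacent liver and 10.01 ± 1.18 in tumours (SD, n = 3). Second probes did not fall with the one reported for Nlrp12 (−0.01), Ugt1a2 (−0.09) and Cpsf4l (0.01 on 1 of its 3 probes). Over 17 alternative settings these decreases passed in 4 (Cpsf4l) to 16 (Ugt1a2), whereas the increases passed in 16 (Rsad2) or 17.

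**Figure D1:**
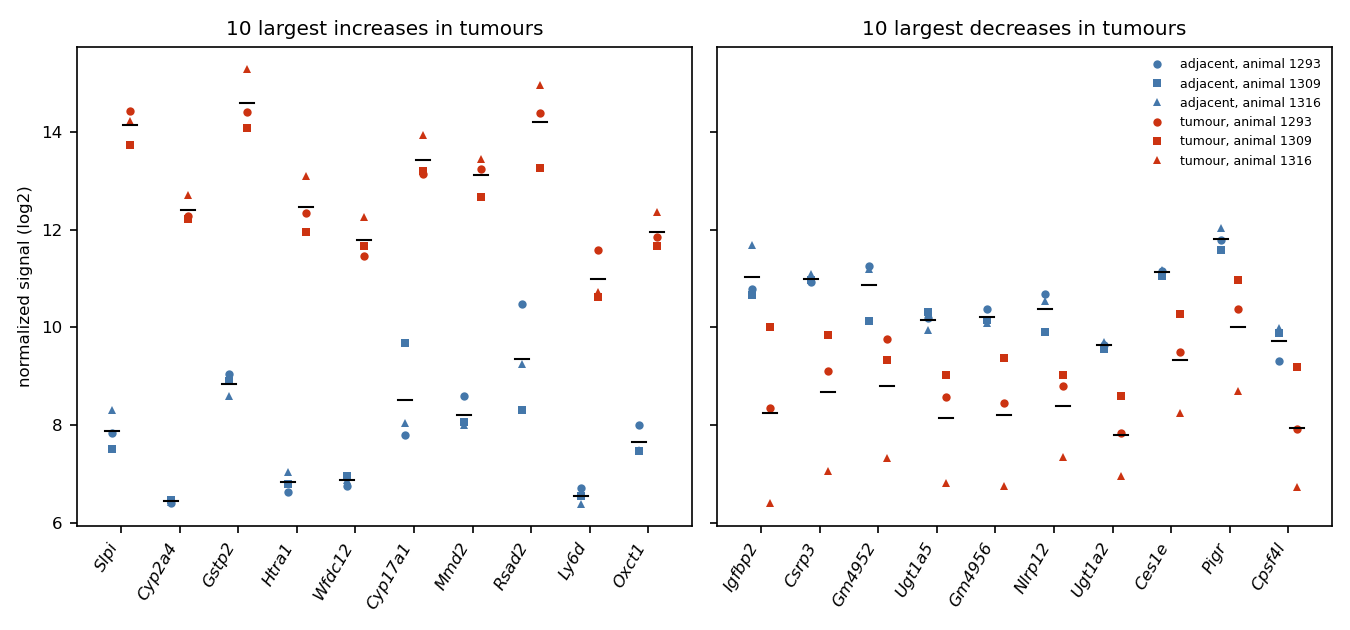
Normalized log2 signal (vertical axis) of the 10 named genes with the largest called increases (left) and decreases (right); each point is 1 array, blue for adjacent liver and red for tumour, the symbol marks the animal, and the bar is the mean of 3. Slpi sits at a mean of 7.89 in adjacent liver and 14.13 in tumours, and among the lowered genes the tumour of animal 1316 is the lowest point.

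In all, 992 of 19057 genes passed an adjusted p of 0.05 with limma, 694 higher and 298 lower in tumours, and each of the 992 differed in the same direction in all 3 animals. With 3 arrays per group a call at this threshold makes a shared direction likely, so it is no separate support. An increase of at least 2-fold was called for 354 genes and a decrease of that size for 111. An increase of at least 8-fold was called for 42 genes, and a decrease of at least 8-fold for 0, while 3644 genes had an unadjusted p under 0.05. With the animal as a replicate block, 1461 genes passed, 868 higher and 593 lower. Of these, 986 were also called without the block. With the animal as a random effect instead, 1139 genes passed, 761 higher and 378 lower. Among all probes 1561 passed, 1041 higher and 520 lower. The fixed block called 2327 probes, of which 1023 were lower, and the random effect 1798, of which 661 were lower. The block named from here on is the fixed one. The share of called genes that were higher was 70.0%, and it was 85.3% when arrays were scaled to their medians and 80.7% without background correction. Leaving out 1 array gave between 446 genes (without the tumour of animal 1293) and 1578 genes (without the tumour of animal 1309); without the adjacent liver of animal 1316 there were 495, without that of animal 1309 there were 587, and without the tumour of animal 1316 there were 635. The lower genes moved most, to 51 without the adjacent liver of animal 1316, 60 without the tumour of 1293, 122 without the adjacent liver of 1309, 155 without the tumour of 1316, 159 without the adjacent liver of 1293 and 659 without the tumour of 1309. Higher genes ranged from 386 (without the tumour of 1293) to 919 (without the tumour of 1309), with 444 without the adjacent liver of 1316. The largest fitted changes of all belonged to unnamed probes. ILMN_2620114 and ILMN_1238042, below background in adjacent liver, were at least 162-fold and 101-fold higher in tumours. In all, 185 of the 10396 probes without a single gene symbol were called.

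The second comparison concerned the imprinted Dlk1-Dio3 cluster, at which the vector was aimed. Rian was raised in all 3 tumours. Its single probe was below the background level in adjacent liver (6.18 ± 0.10) and above it on all 3 tumour arrays (8.37 ± 0.35, log2 signal, SD, n = 3), at least 2.72-fold higher, with a fitted log2 difference of 2.19 (SE 0.17, adjusted p = 1.3e-05, limma). Dlk1, a Notch-related growth factor gene of fetal tissues, was below background in adjacent liver and above it on 2 of 3 tumour arrays on 1 probe. That probe passed (adjusted p = 0.0144, limma), but with a tumour array below background no fold is given. Its other probe was below background on all arrays, and with both averaged Dlk1 did not pass (adjusted p = 0.118). Both Rtl1 probes read higher in each tumour than in its own adjacent liver, but were below background in adjacent liver and above it on 1 and 0 tumour arrays, so no fold can be read, and they did not pass over all probes (adjusted p = 0.214 and 0.221). Dio3 (0.22, SE 0.15), Dio3os (−0.14, SE 0.15) and Meg3, the noncoding RNA gene upstream of Rian (−0.03, SE 0.13), did not pass, and their probes were below background in both tissues, where no fold can be read. Of the 6 list members measured, 2 were higher over all probes and 3 with p-values adjusted over the list alone, Rtl1, near background, being the third. All 6 were below background in adjacent liver. As a list the cluster passed the test for higher genes (mean 0.58, median 0.30, adjusted p = 0.00739, camera; adjusted p = 0.211 with an estimated correlation). Rian, the 1 member above background on at least 3 arrays, carries this call. Without it the mean was 0.25 and the list did not pass (adjusted p = 0.122). Members for which no fold can be read enter both tests.

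**Figure D2:**
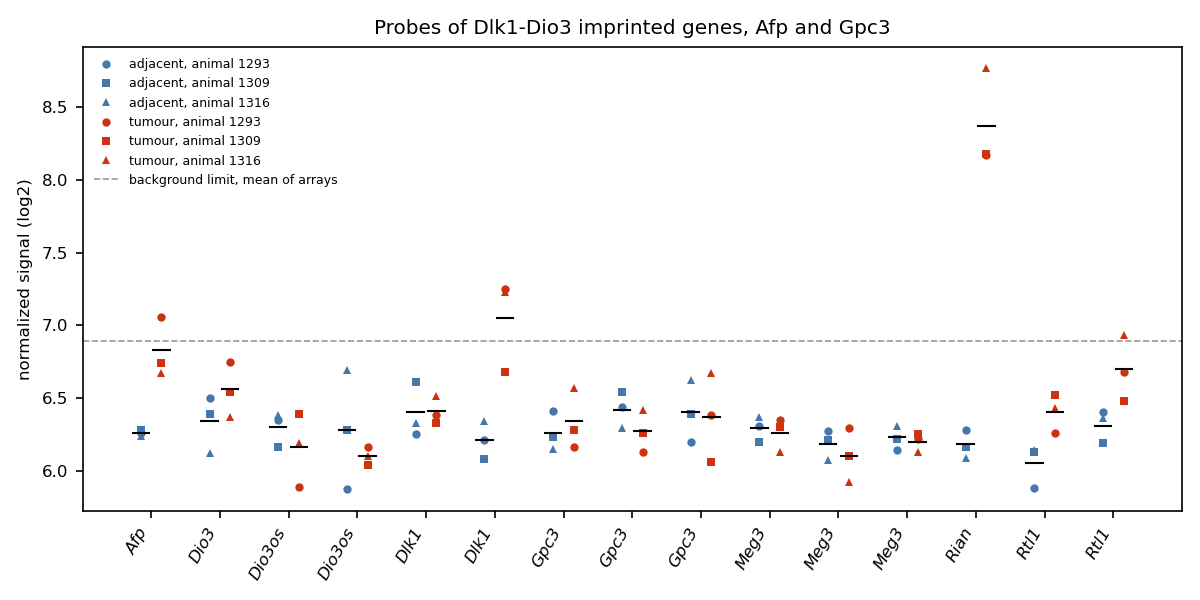
Normalized log2 signal (vertical axis) of each probe of the Dlk1-Dio3 imprinted genes, Afp and Gpc3; each point is 1 array, blue for adjacent liver and red for tumour, the symbol marks the animal, bars are means of 3 and the dashed line is the mean background limit of the arrays. Rian moves from a mean of 6.18 to 8.37, and most other probes stay below the line in both tissues.

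Genes flanking the cluster did not move as a list (mean −0.03, adjusted p = 0.584, camera). Of 17 measured, Hsp90aa1, a cytosolic chaperone gene, rose by 1.10 (SE 0.27), and Ppp2r5c, a phosphatase subunit gene, fell by 0.59 (SE 0.14). The other probes of Hsp90aa1 reached down to −0.40, and those of Ppp2r5c up to −0.05, and neither gene passed with probes averaged (adjusted p = 0.325 and 0.103). Imprinted genes outside the cluster lay higher as a list (mean 0.27, adjusted p = 0.022, camera), with an adjusted p = 0.315 with an estimated correlation. Of 22 measured, 4 rose: Igf2, the fetal growth factor, by 2.61 (SE 0.18, adjusted p = 5.28e-06), Phlda2, which was at least 1.80-fold higher, Impact by 1.01 (SE 0.21) and Grb10, an adaptor of the insulin receptor, by 0.64 (SE 0.14). The other probe of Impact read 0.17 and those of Grb10 reached down to −0.08, and neither gene passed with probes averaged (adjusted p = 0.0841 and 0.437). Ndn was at least 1.29-fold lower and below background on all 3 tumour arrays.

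The liver cancer markers Afp and Gpc3 stayed near background. Afp, alpha-fetoprotein, passed the test (adjusted p = 0.0424, limma) but was above background on 1 tumour array only, so no fold can be read, and Gpc3 was below it on all arrays (−0.03, SE 0.17). Oncofetal and liver tumour markers, with Afp, Gpc3 and Dlk1 among them, were higher as a list (mean 0.95, median 0.30, adjusted p = 1.23e-07, camera), with an adjusted p = 0.160 with an estimated correlation. Only 8 of the 21 members were above background on at least 3 arrays. Of 21 measured, 8 rose and 0 fell, with 9 rising under the animal block. The risen members count Afp and Dlk1, both near background. They also included Ly6d, the tetraspanin gene Cd63 by 3.81 (SE 0.22) and the trefoil factor gene Tff3 by 2.94 (SE 0.27), beside Igf2.

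Genes of the cell cycle formed the largest raised group. Of 40 measured, 22 rose and 0 fell, and 31 rose with p-values adjusted over the list alone (mean 1.08, adjusted p = 4.52e-25, camera; adjusted p = 0.211 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at least 5.94-fold higher in tumours, the phosphatase gene Cdkn3 at least 4.84-fold and the mitotic kinase gene Plk1 at least 3.55-fold, each from below background in adjacent liver. Other probes of Cdc20 rose by as little as 1.13. Prc1, needed for the central spindle, rose by 2.97 (SE 0.23) on 1 probe, which was above background on 1 of 3 adjacent arrays. Another Prc1 probe differed by −0.10. Of 17 p53 target genes 2 rose, Ckap2 (at least 1.47-fold) and Trp53inp1 by 0.94 (SE 0.22), and the list did not pass (adjusted p = 0.0904, camera). Genes of MYC and ribosome biogenesis passed as a list (mean 0.22, adjusted p = 0.00761, camera; adjusted p = 0.426 with an estimated correlation) with 0 of 22 members called, 5 with p-values adjusted over the list alone, and a mean difference of −0.02 in animal 1309. Rrp12 read 0.66 higher (SE 0.17, adjusted p = 0.0503) and Nop58 0.64 higher (SE 0.16, adjusted p = 0.0523); both passed under the block (adjusted p = 0.0478 and 0.0439), while Myc, above background on 1 tumour array, did not (adjusted p = 0.0519, and 0.058 with the block). The other probe of Nop58 (−0.09) did not rise.

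Of 29 targets of NRF2, the transcription factor of the response to oxidants, and glutathione genes, 9 rose and 2 fell (mean 0.71, median 0.28, adjusted p = 3.09e-05, camera; adjusted p = 0.267 with an estimated correlation). Cbr3, a carbonyl reductase gene, rose by 3.56 (SE 0.20), Gsta2 by 3.13 (SE 0.27), Srxn1, which repairs oxidised peroxiredoxins, by 2.74 (SE 0.17) and the export pump gene Abcc4 by 2.53 (SE 0.17), while Ces1g fell by 1.41 (SE 0.28) and Gstt1 by 0.70 (SE 0.17). Immediate early and heat shock genes passed (7 of 20 rose, 0 fell, mean 0.53, adjusted p = 6.62e-05, camera; adjusted p = 0.160 with an estimated correlation), among them the small heat shock protein gene Hspb1 by 2.03 (SE 0.17) on 1 of 2 probes, Fos by 1.83 (SE 0.20), Dusp1 by 0.98 (SE 0.17) and Atf3, which was at least 2.28-fold higher. The unfolded protein response did not pass as a list (adjusted p = 0.54), but 5 of its 21 members rose, among them Asns, asparagine synthetase, by 3.26 (SE 0.33), Ddit3 by 2.14 (SE 0.21) and Trib3 by 1.83 (SE 0.38), with other probes of Asns and Trib3 as low as 0.53 and 0.75. The gene for glutathione transferase Gstp2 and that for Cyp2a4 have near-identical relatives, so their probes can read more than 1 transcript. The same holds for the Gsta, Ugt1a and Cyp2c genes. The Cyp2a4 probe read 6.44 in adjacent liver, below background, where Cyp2a5 read 14.04, so it did not pick up Cyp2a5 there.

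Genes induced by interferon were higher as a list (mean 0.97, adjusted p = 2.16e-12, camera; adjusted p = 0.211 with an estimated correlation). Of 29 measured, 8 rose and 0 fell, and 13 rose with the animal as a block. Beside Rsad2, Oasl1 rose by 2.88 (SE 0.29), Isg15 by 2.62 (SE 0.26) and Ifit3 by 2.46 (SE 0.26). The SD over adjacent livers was 1.08 for Rsad2, 0.28 for Oasl1, 0.27 for Isg15 and 0.03 for Ifit3 (n = 3). Antigen presentation genes of the MHC passed as a list (mean 0.36, adjusted p = 0.0307, camera; adjusted p = 0.498 with an estimated correlation) with 0 of 14 members called, and 5 called under the block. The list passed in 10 of 17 alternative settings. Cd74, the invariant chain, read 1.10 higher (SE 0.30, adjusted p = 0.0729, and 0.0024 with the block).

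Some metabolic lists were called higher. Of 17 genes of glycolysis and the pentose phosphate pathway 7 rose and 1 fell (mean 0.34, median 0.05, adjusted p = 0.00525, camera; adjusted p = 0.211 with an estimated correlation). Pfkp, the platelet form of phosphofructokinase, was at least 4.22-fold higher, the glucose transporter gene Slc2a1 rose by 1.65 (SE 0.21), Aldoa by 1.24 (SE 0.18) and Pkm by 1.09 (SE 0.13), while the kinase gene Pdk1 fell by 1.69 (SE 0.38). Urea cycle and amino acid genes passed (11 of 31 rose, 2 fell, mean 0.41, adjusted p = 7.79e-05, camera; adjusted p = 0.160 with an estimated correlation). Agxt, of glyoxylate metabolism, rose by 1.76 (SE 0.21), Cth and Cbs of transsulfuration by 1.73 (SE 0.23) and 1.21 (SE 0.19), and Aass, of lysine breakdown, by 1.08 (SE 0.15), while Otc of the urea cycle fell by 0.80 (SE 0.19) and Upb1 by 0.48 (SE 0.12, adjusted p = 0.0491, and 0.0565 with the block). Periportal genes did not pass as a list (adjusted p = 0.0835) although 6 of 16 rose, led by Aldh1b1 at 2.70 (SE 0.27), and Ass1 rose by 0.81 (SE 0.15). Genes of lipid droplets and fatty acid uptake passed (4 of 19 rose, 1 fell, mean 0.36, adjusted p = 0.0383, camera; adjusted p = 0.257 with an estimated correlation). Lpl, lipoprotein lipase, rose by 3.15 (SE 0.36) and Hilpda by 1.85 (SE 0.29), Vldlr was at least 2.64-fold and Cidec at least 2.22-fold higher, and Mgll, a monoglyceride lipase gene, fell by 1.48 (SE 0.34). In the gluconeogenesis and glycogen list, which did not pass (adjusted p = 0.864), Ppargc1a rose by 2.08 (SE 0.18), G6pc by 0.80 (SE 0.13) and Fbp1 by 0.85 (SE 0.17), and Pcx fell by 0.58 (SE 0.13), with 5 of 17 lower under the block. Other probes of Pfkp rose by as little as 0.18. Other probes of Lpl (−0.14), Vldlr (−0.22), Ppargc1a (−0.10), Cth (−0.11) and Pkm (−0.08) did not rise, and those of Otc and Pdk1 fell by as little as 0.01 and 0.16.

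Genes with sex-biased expression in mouse liver moved in both directions. Male-biased genes were lower as a list (mean −0.79, adjusted p = 2.56e-06, camera; adjusted p = 0.326 with an estimated correlation), with 2 of 25 called lower, or 12 with the animal as a block. The list mean was −0.64, −0.31 and −1.41 in animals 1293, 1309 and 1316. Susd4 fell by 1.66 (SE 0.38) and Cyp2u1 by 0.61 (SE 0.12). Other probes of Cyp2u1 reached 0.13, and averaged over its probes it did not pass (−0.14, adjusted p = 0.614). Female-biased genes were higher (mean 0.75, adjusted p = 0.0275, camera; adjusted p = 0.234 with an estimated correlation). Their median was 0.01 and 4 of 19 rose: Cyp2a4, Cyp17a1, the neurotrophin receptor gene Ntrk2 by 4.06 (SE 0.26) on 1 of 4 probes, and Cyp2b13 (adjusted p = 0.041, limma). Cyp2b13 was below background in adjacent liver and above it on 2 of 3 tumour arrays, so no fold is given.

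Other lists of hepatocyte genes were lower, unlike the urea cycle and amino acid list, and each of these had its largest fall in animal 1316. Cytochrome P450 and other phase I genes passed (mean −0.60, adjusted p = 0.00135, camera; adjusted p = 0.355 with an estimated correlation), with 3 of 33 lower, or 11 under the block, and 2 higher. Cyp3a25 fell by 1.63 (SE 0.37) and Cyp2d26 by 0.86 (SE 0.16), and against the trend Cyp2b10 rose by 3.93 (SE 0.21; 0.69 on its other probe) and Cyp2a5 by 1.05 (SE 0.21). Targets of beta-catenin and other pericentral genes were lower (mean −0.66, adjusted p = 0.00562, camera; adjusted p = 0.460 with an estimated correlation), with Rgn falling by 1.04 (SE 0.24) and Oat rising by 0.63 (SE 0.14) as the only called members of 20. These calls passed in 4 and 9 of 17 alternative settings. Under the block 5 members were lower. Bile acid genes were lower (5 of 23 fell, 8 under the block, mean −0.42, adjusted p = 0.000102, camera; adjusted p = 0.301 with an estimated correlation), among them the uptake transporter gene Slc10a1 by 0.99 (SE 0.21), the phospholipid pump gene Abcb4 by 0.99 (SE 0.21), Slco1a4 by 0.83 (SE 0.18; −0.08 on its other probe) and Abcc3 by 0.72 (SE 0.16), while Abcc4, also in the NRF2 list, rose.

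Fatty acid and triglyceride synthesis was lower (4 of 23 fell, 9 under the block, mean −0.58, adjusted p = 0.000878, camera; adjusted p = 0.460 with an estimated correlation): Acss2 fell by 1.18 (SE 0.22), Mlxipl, the carbohydrate-responsive factor, by 1.15 (SE 0.24), Gpam by 0.98 (SE 0.21; 0.12 on its other probe) and Fasn, fatty acid synthase, by 0.89 (SE 0.20), while Dgat1 rose by 0.88 (SE 0.12). Fatty acid oxidation and PPAR-alpha targets were lower (4 of 24 fell, 7 under the block, mean −0.47, adjusted p = 0.00052, camera; adjusted p = 0.211 with an estimated correlation), among them Cyp4a31 by 1.77 (SE 0.41), Acaa1b by 1.10 (SE 0.22), Ehhadh by 0.67 (SE 0.14) and Bdh1 by 0.67 (SE 0.13). Secreted plasma protein genes were lower (5 of 36 fell, 1 rose, mean −0.24, adjusted p = 0.000175, camera; adjusted p = 0.295 with an estimated correlation). The coagulation factor gene F7 fell by 1.04 (SE 0.18), Rbp4, the carrier of retinol, by 0.96 (SE 0.20) and Proc by 0.72 (SE 0.15), and Itih2 rose by 1.05 (SE 0.16). The single Alb probe, which fell by 0.84 (SE 0.15), read 7.71 in adjacent liver, near background, and is no measure of albumin abundance. Hepatocyte transcription factors were lower (mean −0.32, adjusted p = 0.0082, camera; adjusted p = 0.321 with an estimated correlation) with 0 of 18 called lower and Hes6 rising by 1.08 (SE 0.21).

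Among other lists without a call in the unblocked fit were cholesterol synthesis (mean −0.24, adjusted p = 0.0645; 0.0252 with the block), in which Tm7sf2 fell by 1.16 (SE 0.23), and acute phase genes (mean −0.43, adjusted p = 0.0573; 0.00278 with the block), in which Il1rn was at least 1.32-fold higher on 1 of 4 probes (another read −0.08) and 8 of 27 members were lower and 2 higher under the block. No call was made either for the growth hormone and insulin-like growth factor axis (mean −0.19, adjusted p = 0.464), iron handling (mean 0.10, adjusted p = 0.87; 3 of 16 members higher and 1 lower under the block) and the circadian clock (mean −0.24, adjusted p = 0.395), all by camera. Over 17 alternative settings, the block included, the cholesterol list passed in 5 and the acute phase list in 7. In all, 13 of 38 lists passed as higher and 8 as lower, or 14 and 10 with the block, and 0 passed with an estimated correlation. That form raised p-values even where the estimate was under the preset 0.01. For immediate early and heat shock genes (estimate −0.002) the unadjusted camera p went from 1.05e-05 to 0.00859. Other estimates were high, such as 0.415 for cell cycle genes. A call lost in this form is thus no measure of correlation among members alone. A division of the 6 arrays that mixed tumours with adjacent livers gave up to 15 lists past camera at the preset correlation, against 21 in the real comparison. Such a division keeps part of the difference between the tissues, so its count is no measure of false calls.

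**Figure D3:**
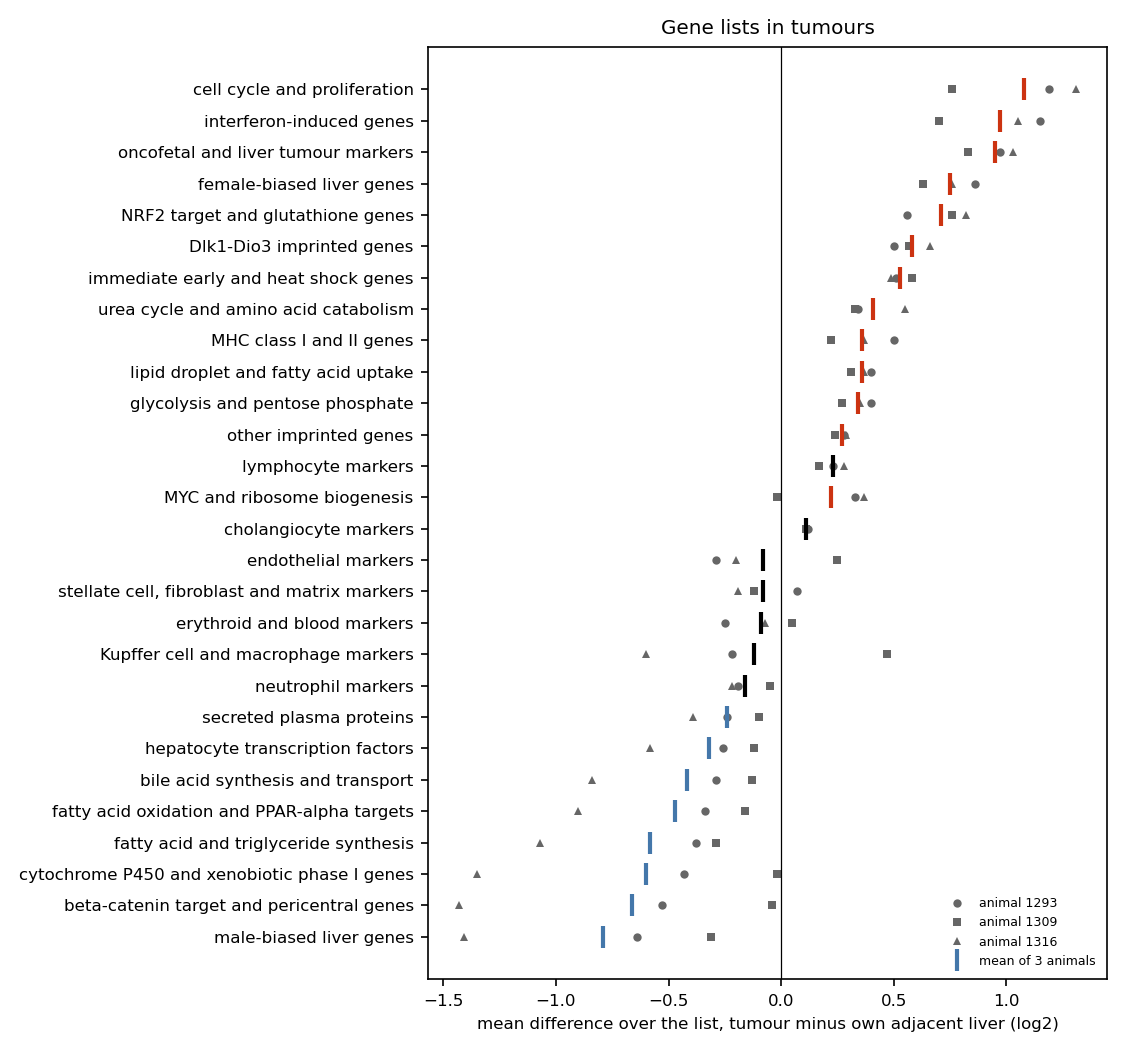
Mean log2 difference over each gene list, tumour minus the same animal's adjacent liver (horizontal axis), for lists past the camera test and for cell type markers; grey symbols are single animals and the upright bar is the mean of 3, red for lists called higher, blue for lists called lower and black for lists not called. Cell cycle genes have the highest mean, 1.08, and male-biased genes the lowest, −0.79, with animal 1316 farthest to the left in each lowered list.

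Markers of other cell types showed no call as lists in the main fit: cholangiocytes (mean 0.11, adjusted p = 0.742), stellate cells, fibroblasts and matrix (mean −0.08, adjusted p = 0.245), endothelium (mean −0.08, adjusted p = 0.366), Kupffer cells and macrophages (mean −0.12, adjusted p = 0.366), lymphocytes (mean 0.23, adjusted p = 0.0666, and 0.0384 with the block), neutrophils (mean −0.16, adjusted p = 0.318) and red blood cells (mean −0.09, adjusted p = 0.507), all by camera. Above background on at least 3 arrays were 4 of 14 cholangiocyte, 3 of 18 lymphocyte, 3 of 12 neutrophil and 5 of 9 red blood cell markers. For these cell types a missing call says little. The endothelial and macrophage lists each passed in 1 of 17 alternative settings, and the lymphocyte list in 2 of 16. Single members did move. Of 22 Kupffer cell and macrophage markers 2 were called higher and 0 lower, but with p-values adjusted over the list alone 4 were higher and 4 lower. Gpnmb, a gene of lipid-laden macrophages, was at least 6.89-fold higher in tumours on 1 of 4 probes (another read −0.11), Cd14 rose by 2.05 (SE 0.28), the chemokine gene Ccl5 by 2.27 (SE 0.32) and the keratin gene Krt18, which hepatocytes also express, by 1.26 (SE 0.21). In the matrix list Col4a1 of basement membrane rose by 1.15 (SE 0.28) and Col4a2 from 8.89 ± 0.27 to 9.88 ± 0.40 (log2 signal, SD, adjusted p = 0.0165, limma), while Reln, Ecm1, Dcn and Bgn fell by 1.25, 1.39, 0.93 and 0.60. Other probes of Reln reached 0.22 and those of Dcn −0.15, and averaged over its probes Reln did not pass (−0.21, adjusted p = 0.549). The macrophage list differed between animals, with mean differences of −0.22, 0.47 and −0.60 in animals 1293, 1309 and 1316, and the endothelial list likewise with −0.29, 0.25 and −0.20.

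The third comparison asked how far the 3 tumours changed the same genes. Differences between each tumour and its own adjacent liver correlated across 8336 expressed genes, which are not independent replicates, at r = 0.79 for animals 1293 and 1309, 0.81 for 1293 and 1316 and 0.75 for 1309 and 1316. By more than 1 log2 unit, 408, 250 and 631 genes were higher in the tumours of animals 1293, 1309 and 1316, 204 of them in all 3 and 268 in animal 1316 alone. Lower by as much were 198, 14 and 588 genes, of which 5 in all 3 and 408 in animal 1316 alone. At more than 2 log2 units, 174 genes were lower in animal 1316, 6 in 1293 and 0 in 1309. These are single values per animal, without a test. The list means followed this order: the P450 list differed by −0.43, −0.02 and −1.35 in animals 1293, 1309 and 1316, and the pericentral list by −0.53, −0.04 and −1.43, whereas the cell cycle list rose in each, by 1.19, 0.76 and 1.31.

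**Figure D4:**
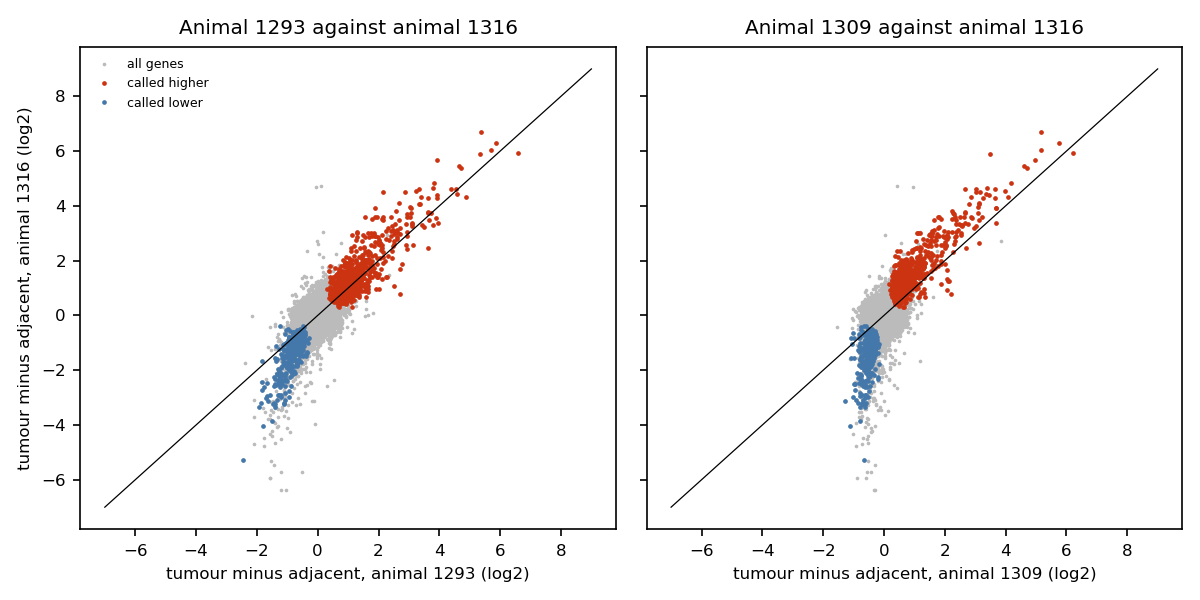
Log2 difference between tumour and own adjacent liver per gene in animal 1316 (vertical axis) against animal 1293 (left) and animal 1309 (right); grey points are all genes, red and blue those called higher and lower, and the line marks equal differences. Lower by more than 1 log2 unit are 588 genes in animal 1316, against 198 in animal 1293 and 14 in animal 1309.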

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

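The offset of 16, the filter on dim probes, the block without animal 1316 and the Dlk1-Dio3 list without Rian were chosen after seeing the data; the other settings were fixed before. No called gene turned its sign under any of the 16 refits with other values, arrays or models, but their number moved, the lower calls most, and the cause was not tested except where a setting uses fewer arrays or fewer probes. Neqc at an offset of 16 and a filter on detection p-values, the first choice of the plan, could not be run on this table. Normexp at an offset of 50 without a filter, planned for such a table, is the main setting.

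Genes called were 992, 694 higher and 298 lower, and probes 1561, 1041 and 520. With the replicate block 593 genes and 1023 probes were lower, and with the animal as a random effect 378 and 661. Without background correction 653 genes were called, 126 lower, and 1012 probes, 244 lower, and the authors' processed values gave these same counts. Median scaling left 130 lower genes and 227 lower probes. The offset of 16 gave 506 genes (448 higher, 58 lower) and 787 probes (677 and 110). The filter on dim probes left 175 lower genes, 325 lower probes and 8 higher lists. Without both arrays of animal 1316 there were 401 genes (337 and 64) and 620 probes (507 and 113). The block on these 4 arrays was run and set aside: it leaves 1 residual degree of freedom, and limma then estimated 458 prior degrees of freedom against 7.09 to 9.45 in the other fits, so its 1296 called genes are not used. Over the 6 fits without 1 array, genes ranged from 446 to 1578, higher genes from 386 to 919, lower genes from 51 to 659, probes from 666 to 2509, higher probes from 566 to 1404, lower probes from 100 to 1105 and higher lists from 8 to 13. An adjusted p of 0.10 gave 1510 genes (585 lower) and 2453 probes (1045 lower). A minimum of 1 log2 unit left 465 genes (354 and 111) and 703 probes (524 and 179). Averaging the probes of a gene gave 556 genes (452 and 104). Of the 992 genes, 986 stayed called with the block, 614 without background correction, 506 at the offset of 16 and 377 without animal 1316.

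Camera with an estimated correlation called 0 lists higher and 0 lower, and fry, which tests whether a list's genes move one way, called 15 higher and 0 lower (the Dlk1-Dio3 list among the 15, adjusted p = 0.00725). Of the 21 lists called by camera, 16 passed in every refit that could test them. The others were MHC genes (10 of 17 refits), lipid droplets and fatty acid uptake (11), female-biased genes (14), MYC and ribosome biogenesis (15) and other imprinted genes (15). The Dlk1-Dio3 list, mean 0.58, passed in the 16 refits that could test it (adjusted p between 0.00228 and 0.022), but all of these hold Rian and members below background, and the filter on dim probes left too few members to test. Its call was lost without Rian (mean 0.25, adjusted p = 0.122), which shows that Rian carries it, and with an estimated correlation (adjusted p = 0.211). That estimate was −0.043, under the preset 0.01, so the loss with it does not show that members vary together. Genes higher in all 3 tumours were 449 at 0.58 log2 units and 61 at 2, genes lower in all 3 were 130 and 0, those lower in animal 1316 alone 856 and 170, and those higher there alone 738 and 55. Of the called genes chosen by the naming rule, the 72 higher passed in a median of 17 of 17 settings (lowest 5) and the 46 lower in a median of 8 (lowest 4). Rian passed in 17 of 17 settings, and Dlk1 in 9 and Afp in 7 of the 16 that measured them. With probes averaged, of the called genes that have a disagreeing probe, Nlrp12, Cpsf4l, Dlk1, Ppp2r5c, Hsp90aa1, Impact, Grb10, Otc, Cyp2u1, Slco1a4, Gpam, Pdk1, Il1rn, Trib3, Reln and Dcn no longer passed (adjusted p from 0.0564 to 0.614). Below background a fall cannot be read, and a rise only once it passes that level, which no probe of Meg3, Dio3 or Gpc3 did.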

Other observations

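Further groups outside the fixed lists were picked after their values were seen. Slpi and Wfdc12 belong to the whey acidic protein family, and 2 more members, Wfdc15b and Wfdc3, were below background in adjacent liver and at least 13.6-fold and 8.72-fold higher in tumours, the latter on 1 of 2 probes. The family did not move as one: Wfdc1 fell by 1.08 (SE 0.18), and Wfdc2 and Wfdc21 read lower by 1.76 (SE 0.47, adjusted p = 0.0691) and 1.82 (SE 0.53, adjusted p = 0.0955), past the threshold with the animal as a block (adjusted p = 0.0444 and 0.0131). Secreted or signalling factors also appeared from below background: Il33, an alarmin cytokine, at least 11.9-fold, Fst, the activin antagonist follistatin, at least 8.83-fold, and Wnt10a at least 4.07-fold higher. Nupr1, a stress-induced chromatin protein gene, rose by 4.13 (SE 0.34), the galectin gene Lgals3 by 3.66 (SE 0.26), Gpx3, a secreted glutathione peroxidase gene, by 3.51 (SE 0.21) and the tetraspanin gene Cd9 by 2.96 (SE 0.18). Among lowered genes outside the lists, the lysosomal protease gene Ctsa fell by 1.61 (SE 0.24), Sucnr1, a succinate receptor gene, by 1.40 (SE 0.18) and Sort1 by 1.46 (SE 0.28), all in limma at an adjusted p under the threshold. No chromosome moved as a whole: over 20 chromosomes and 3 tumours, median differences of expressed genes lay between −0.11 and 0.07.

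Of the tests reported here, the mixing test, the test against probes of like signal, the joint test of neighbours and the splits counting probes and genes were chosen after the result was seen; the others were written before. The 7 lists of hepatocyte genes called lower other than the male-biased genes fell further in the tumour of animal 1316 than in the others, whereas the urea cycle and amino acid list rose there by 0.55 (0.34 and 0.33 in animals 1293 and 1309). Over 112 bright members of the 7 lists, in signals not normalized between arrays, the median difference was −0.41, −0.13 and −0.62 in animals 1293, 1309 and 1316. Less the median of the 200 probes nearest in signal, the further fall in 1316 had a median of −0.35 (10th to 90th percentile −3.47 to 0.25). The lowest of 1000 draws of as many probes of like signal was −0.13. An effect of the array that acts alike on probes of like signal would leave no such gap. However, the 7 lists were chosen because they were called lower in these arrays. The draws also took probes singly, whereas list members vary together. The draws thus overstate how unusual the gap is, and such an effect is not excluded. Against each of the 3 adjacent livers, 523 to 588 genes were lower by over 1 log2 unit in tumour 1316, so the choice among these livers mattered little. The 3 livers correlate at 0.983 to 0.985 with each other, so similar counts were likely from the start. The animal number in the conflicting label has no adjacent liver among the arrays, so a wrong pairing is not excluded. Adjacent liver mixed into the tumour samples of animals 1293 and 1309 may contribute. Its share was read from 63 probes, bright in all adjacent livers, that were chosen for keeping under 0.06 of their signal in tumour 1316, and that kept medians of 0.279 in animal 1293 and 0.564 in 1309. It predicts rises of 0.721 and 0.436 of those in 1316, and the 524 raised probes had medians of 0.711 and 0.474 (10th to 90th percentile 0.426 to 1.33 and 0.276 to 0.762). Tumours that differ in how far they have changed would give smaller falls and rises together too, which stays open with 1 array per tumour, and no biological explanation was tested.

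Genes raised at least 2-fold lay next to each other in gene order more often than shuffled genes did: 23 adjacent pairs among 354 genes, such as Rsad2 with Cmpk2, Batf3 with Atf3, Oip5 with Nusap1 and Plekha1 with Htra1, against a mean of 6.52 and a highest of 15 in 1000 shuffles. Shared probe signal between near-identical neighbours, such as Ifit2 with Ifit3, does not account for all of it alone, as 15 pairs outside name families remained against a highest of 14. Expressed genes lying together do not either, as shuffling among genes of like signal reached 19. With both applied at once, 15 pairs stood above the 95th percentile of 12 but under the highest of 19, so that combination stays open, and shared regulation of neighbours remains a hypothesis that was not tested.

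The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so chance cannot be judged this way. Only the real split, 1 of the 10, gave as many calls: 1561 probes against a highest other of 5, 992 genes against 3, and 21 lists against 15. The same held among the 4 splits that part all 3 animals' pairs, where the others called 0 probes, 0 genes and up to 15 lists. Each other split keeps part of the difference between the tissues.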
